A study of Drosophila melanogaster with 6 samples.

How the data were processed

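RNA was measured in 6 samples of *Drosophila melanogaster* stage 14 oocytes, the last stage before an egg is laid. Per the labels, 3 samples were GFP controls and 3 expressed InR-DN, which the submitters use to suppress insulin signalling, and each sample was a pool of 200 oocytes. The labels describe the RNA as polyA selected, while the extraction protocol names a stranded total RNA kit, so the way in which ribosomal RNA was removed is not settled by the labels. The submitters' processing notes name FastQC, Bowtie and TopHat without versions. A genome build and a read counter are not given in the sources used here.

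The only values analysed here are those of the authors' deposited table, a comparison of 2 groups with 14862 genes. Per the file headers, it holds for each gene a log2 fold change, an average log2 CPM (read counts scaled to library size), a likelihood ratio score, a p-value and an adjusted p-value, all computed by the authors. The title of the authors' deposited table holds the name of edgeR's likelihood ratio test, and it calls the samples embryos. The labels name stage 14 oocytes as the source of all 6 samples, but the description of the InR-DN samples also uses the word progeny, which the labels do not explain. Values per sample were not analysed here, so the depth of each sample is unknown, no error between replicates could be computed, and no gene was tested anew. The labels do not say whether the 3 pools of a group came from separate crosses, so the authors' p-values measure only the spread between the samples in their fit, which may be technical. The analysis planned before the data were examined named a count test for the case of a count table, and the authors' own adjusted p-values for a table of this kind, which were therefore used. A set test on log2 CPM per sample had also been planned and was replaced as described below.

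The direction of the deposited fold changes is not stated in the header of the table. Fold changes are therefore given as positive or negative, as the authors deposited them, and are not assigned to the GFP control or to the InR-DN oocytes.

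The deposited p-values were checked against the chi-square tail of the likelihood ratio score with 1 degree of freedom, from which they differed by at most 6.4e-15. The adjusted p-values of the authors were checked against a Benjamini-Hochberg adjustment over all 14862 genes, from which they differed by at most 3.6e-15. A fold change of 0, a likelihood ratio of 0 and a p-value of 1 were listed for 1782 genes, and the other 13080 genes are called tested genes. A gene was called when its deposited adjusted p was under 0.05. An SE was implied for each gene by dividing the size of its log2 fold change by the square root of its likelihood ratio score, where that score was above 0.0001, and a 95% interval was taken as 1.96 of these SE on either side. This implied SE rests on the authors' model and is not a spread measured between samples. It does not measure the precision of the largest fold changes, for which 1 group may hold few reads or none.

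Before the data were examined, 31 lists of genes were fixed. They cover insulin signalling and its targets, carbohydrate, lipid and mitochondrial metabolism, ribosomes, proteasome and autophagy, maternal and meiotic regulators, piRNA and chromatin factors, stress and immune genes, early zygotic genes, and markers of 9 tissues or cell types that can accompany an oocyte. Of their members, 18 were found under a synonym in the RefSeq gene table of the Release 6 plus ISO1 MT assembly and 13 were not found. That gene table, which matched 14707 of the 14862 gene names, was used for names and for the order of genes along chromosomes, and no coordinates are given because the authors' build is unknown. Lists with 5 or more tested members were tested with cameraPR of limma 3.58.1 in R 4.3.3, on the square root of the likelihood ratio score with the sign of the fold change, against all other tested genes. Its preset inter-gene correlation of 0.01 was kept because a correlation cannot be estimated without values per sample. The p-values of the lists were adjusted by the Benjamini-Hochberg method. The set test was tried on the scores of the 13080 genes after shuffling, with 5 lists moved in each of 100 rounds. It recovered 23% of lists moved by 0.5 SD, 97% of lists moved by 1 SD and 0.40% of lists that were not moved. Shuffled scores hold no correlation between genes and these lists shared no gene, so the rates may differ for lists of co-expressed genes. Random lists matched on average log2 CPM, over 20 bins of abundance, were drawn 10000 times. Tables were read and drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

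The rule for the genes named in the text was also fixed before the data were examined. It takes InR, the 10 called genes with the largest positive and the 10 with the largest negative fold change among those with an average of at least 5 CPM, the 5 called genes with the highest average, up to 4 called members of a list that passed the set test or had 3 or more called members, 1 called member of any other list, and the member with the highest average of a marker list with none. A further condition of the rule, that the samples of the 2 groups should not overlap, could not be applied to the authors' deposited table. Any other gene that is named was chosen after its values were seen. Alternatives to the threshold, to the genes entering the adjustment and to the set test were computed, and those that need values per sample were not run.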

Results

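The series asks which genes in the oocyte respond when insulin signalling is suppressed. In *Drosophila melanogaster*, stage 14 oocytes that expressed GFP served as the control, with 3 samples, and were compared with oocytes that expressed InR-DN, with 3 samples. InR is the insulin receptor, and the submitters use InR-DN to suppress its signalling. RNA was sequenced from pools of 200 oocytes. The values are those of the authors' deposited table, which compares 2 groups gene by gene. It gives no values per sample, so the depth behind each value is unknown and the spread between replicates enters only through the authors' own test. The table does not say which group is the numerator, and fold changes are described by their sign alone.

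The receptor gene itself, InR, had a log2 fold change of 0.25 in the authors' deposited table, with an implied SE of 0.26 and an adjusted p of 1. InR had been chosen beforehand as a check of the labels, because reads of the transgene can be counted under it. Its 95% interval ran from -0.25 to 0.75, within a 2-fold change in either direction. InR therefore gave no check of which group was which, and reads of the transgene were not seen through it. Across the transcriptome, 667 of 13080 tested genes passed the authors' adjusted p of 0.05, of which 342 had a positive and 325 a negative fold change. With genes of average log2 CPM below 0 left out before adjustment, an alternative chosen after seeing the data, 209 positive and 135 negative genes passed. Called genes made up 5.10% of those tested, and 490 of them passed an adjusted p of 0.01. The median log2 fold change was 1.75 among the positive and -2.26 among the negative genes, against 0.03 among all tested genes. Most called genes had low averages in the authors' fit: 416 of them, or 62.4%, had an average log2 CPM below 1, and at an average log2 CPM of 8 or more only 2 of 710 tested genes were called. Which libraries enter this average is not stated, and 59 genes with a fold change and a likelihood ratio of 0 had an average log2 CPM above 1. The average is therefore not known to be a level of the compared samples.

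**Figure D1:**
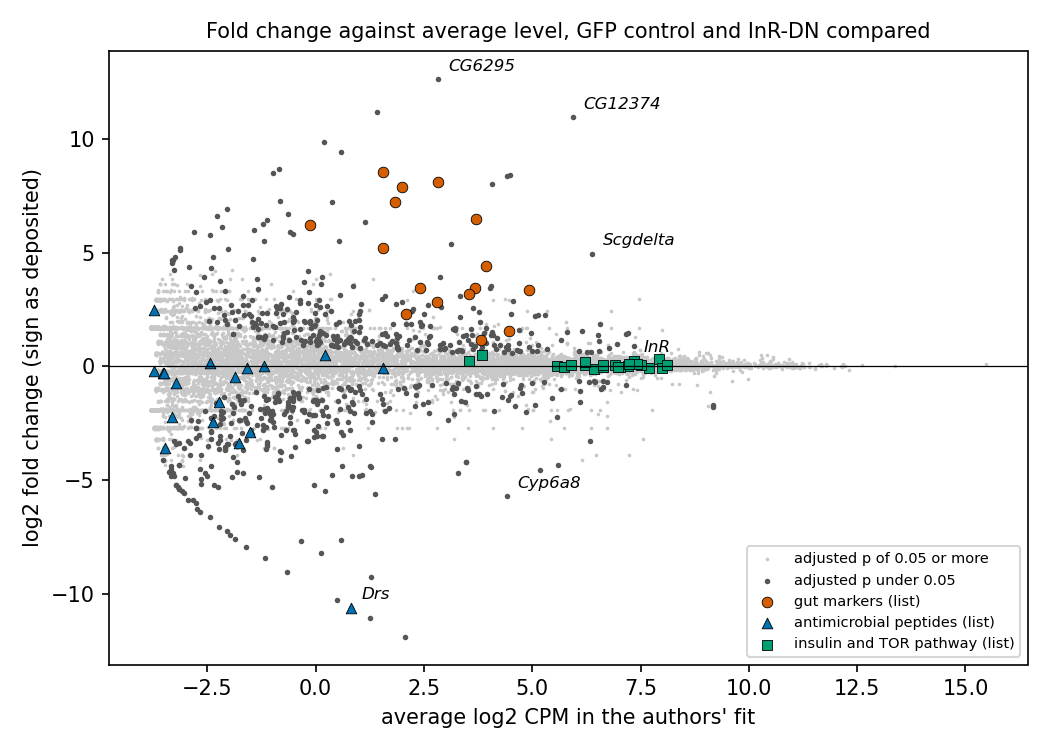
Each point is 1 tested gene of the authors' deposited table, with the average log2 CPM of the authors' fit on the horizontal axis and the log2 fold change, in the sign deposited, on the vertical axis. Dark points are the 667 genes with an adjusted p under 0.05, and coloured symbols are members of 3 gene lists. The 16 gut markers lie between 1.15 and 8.55, the insulin and TOR genes lie between -0.10 and 0.48, and Drs lies at -10.61.

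All 16 tested members of the gut list, which holds genes of digestive enzymes and lysozymes, were called with positive log2 fold changes, from 1.15 to 8.55 with a median of 3.93, and all 16 were also called when adjusted over the list alone. In the authors' deposited table the lysozyme genes LysB and LysD, which act in the digestion of bacteria, had log2 fold changes of 8.55 (implied SE 0.72) and 7.88 (implied SE 0.46). The serine protease genes Jon99Ci and epsilonTry of the gut list were at 8.12 and 7.25 in the authors' deposited table. The list members betaTry and alphaTry, also among the 10 largest positive genes, were at 6.49 and 4.39 in the authors' deposited table. The list passed the set test with an adjusted p of 5.8e-164. That p rests on a preset correlation between genes, which could not be estimated without values per sample. If the members of the list move together more than was preset, the p is too small. Reads shared between related members, such as LysB and LysD, were not excluded, so the 16 calls may not be separate results. Outside the list, the 29 other tested members of the same enzyme families, chosen after the values were seen, had 13 positive calls, 3 negative calls and 13 without a call. The authors' deposited table gave CG6295, a lipase gene, a log2 fold change of 12.64 (implied SE 0.62) and CG12374, a metallocarboxypeptidase gene, 10.96 (implied SE 0.41). The serine proteases Jon25Bi and Jon25Bii were at 8.43 and 8.01 and the aspartic protease Bace at 5.40 in the authors' deposited table. The remaining 2 of the 10 largest positive genes, per the authors' deposited table, were CG30272, a gene of the major facilitator transporter family, at 8.37 (implied SE 0.77) and Scgdelta, which encodes a sarcoglycan of the dystrophin complex, at 4.95 (implied SE 0.48).

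Of 18 antimicrobial peptide genes and their regulators, 5 were called and all 5 had negative fold changes, while 7 were called, all negative, when adjusted over the list alone. The authors' deposited table gave Drs, the antifungal peptide Drosomycin, a log2 fold change of -10.61 (implied SE 0.66). Dpt, Def and DptB, which encode peptides active against bacteria, were at -3.36, -2.88 and -2.45 in the authors' deposited table, with adjusted p of 5.9e-05, 0.016 and 0.0030. The fifth, AttB, named after its value was seen, was at -1.57 in the authors' deposited table. On the same side, 8 of 9 secreted protease genes of the spermatheca, a sperm storage organ, listed after their values were seen, were called with log2 fold changes from -6.39 to -9.03 in the authors' deposited table. The average log2 CPM of these 8 protease genes was low, from -2.67 to 0.13 in the authors' deposited table. The set test gave the antimicrobial list an adjusted p of 2.4e-05. Its median was -0.39, since 13 members were not called and 4 of the 18 had positive fold changes. Their averages were low, with a median average log2 CPM of -2.30, and with genes of average log2 CPM below 0 left out too few members remained for the set test.

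The 10 largest negative fold changes among called genes with an average of at least 5 CPM came from genes of varied function. Whether these genes share a tissue of origin was not tested. In the authors' deposited table Cyp6a8, a cytochrome P450 gene, had a log2 fold change of -5.71 (implied SE 0.59, adjusted p = 1.7e-19). The organic anion transporter gene Oatp58Dc was at -3.26 (implied SE 0.34) and Smvt, a gene of the sodium-dependent multivitamin transporter family, at -2.22 (implied SE 0.37) in the authors' deposited table. The transcription factor genes byn, needed for the hindgut, and ap, needed for the dorsal wing, were at -4.68 and -2.33 in the authors' deposited table, with implied SE of 1.26 and 0.54. CG43163 was at -4.35 and CG9509 at -2.07, and the noncoding gene CR45138 was at -4.54 with an implied SE of 1.29, again per the authors' deposited table. CG17139 and CG17140 shared 1 log2 fold change of -4.21 in the authors' deposited table and overlap in the reference gene table, so their reads cannot be told apart.

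Among genes with high averages the changes were smaller. The 5 called genes with the highest average in the authors' deposited table were CG43355 at -1.80, sala at -1.70, the Hedgehog receptor gene ptc at 0.91, the aldehyde dehydrogenase gene Aldh at 1.45 and Cks30A, a partner of the cell cycle kinase Cdk1 used in female meiosis, at 1.44. Their implied SE were 0.55, 0.55, 0.24, 0.19 and 0.43 in the same order, from the authors' deposited table. The average log2 CPM of CG43355 and sala were both 9.17 in the authors' deposited table, and the call of sala was narrow, with an adjusted p of 0.049. With values this close, reads shared between CG43355 and sala were not excluded, and they may not be separate results.

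The insulin pathway held no called gene. None of 22 tested insulin and TOR pathway genes was called by the authors' likelihood ratio test, none had an unadjusted p under 0.05, and the intervals of 20 of the 21 that had one lay within a 2-fold change in either direction. Among 20 FOXO targets and starvation genes 1 was called, the nutrient-dependent peptide hormone gene CCHa2, at 2.33 in the authors' deposited table (implied SE 0.35). The average log2 CPM of CCHa2 was low, at 0.22 in the authors' deposited table, and whether its reads came from the oocyte was not tested. Genes of glycolysis (14 tested), the tricarboxylic acid cycle (19), complex I (33), complexes II to V (35), fatty acid oxidation (12) and mitochondrial biogenesis (22) had no called member and no unadjusted p under 0.05, with list medians between -0.08 and 0.01. Of 9 glycogen and trehalose genes none was called and 1 had an unadjusted p under 0.05, the trehalose synthesis gene Tps1, which was called when adjusted over the list alone. Tps1, named after its value was seen, was at -0.70 in the authors' deposited table with an adjusted p of 0.085. The lipid list had 1 called member of 20, the fatty acid synthase gene FASN2, listed as v(2)k05816, at 1.25 in the authors' deposited table (implied SE 0.32), and 3 of the 20 had an unadjusted p under 0.05.

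**Figure D2:**
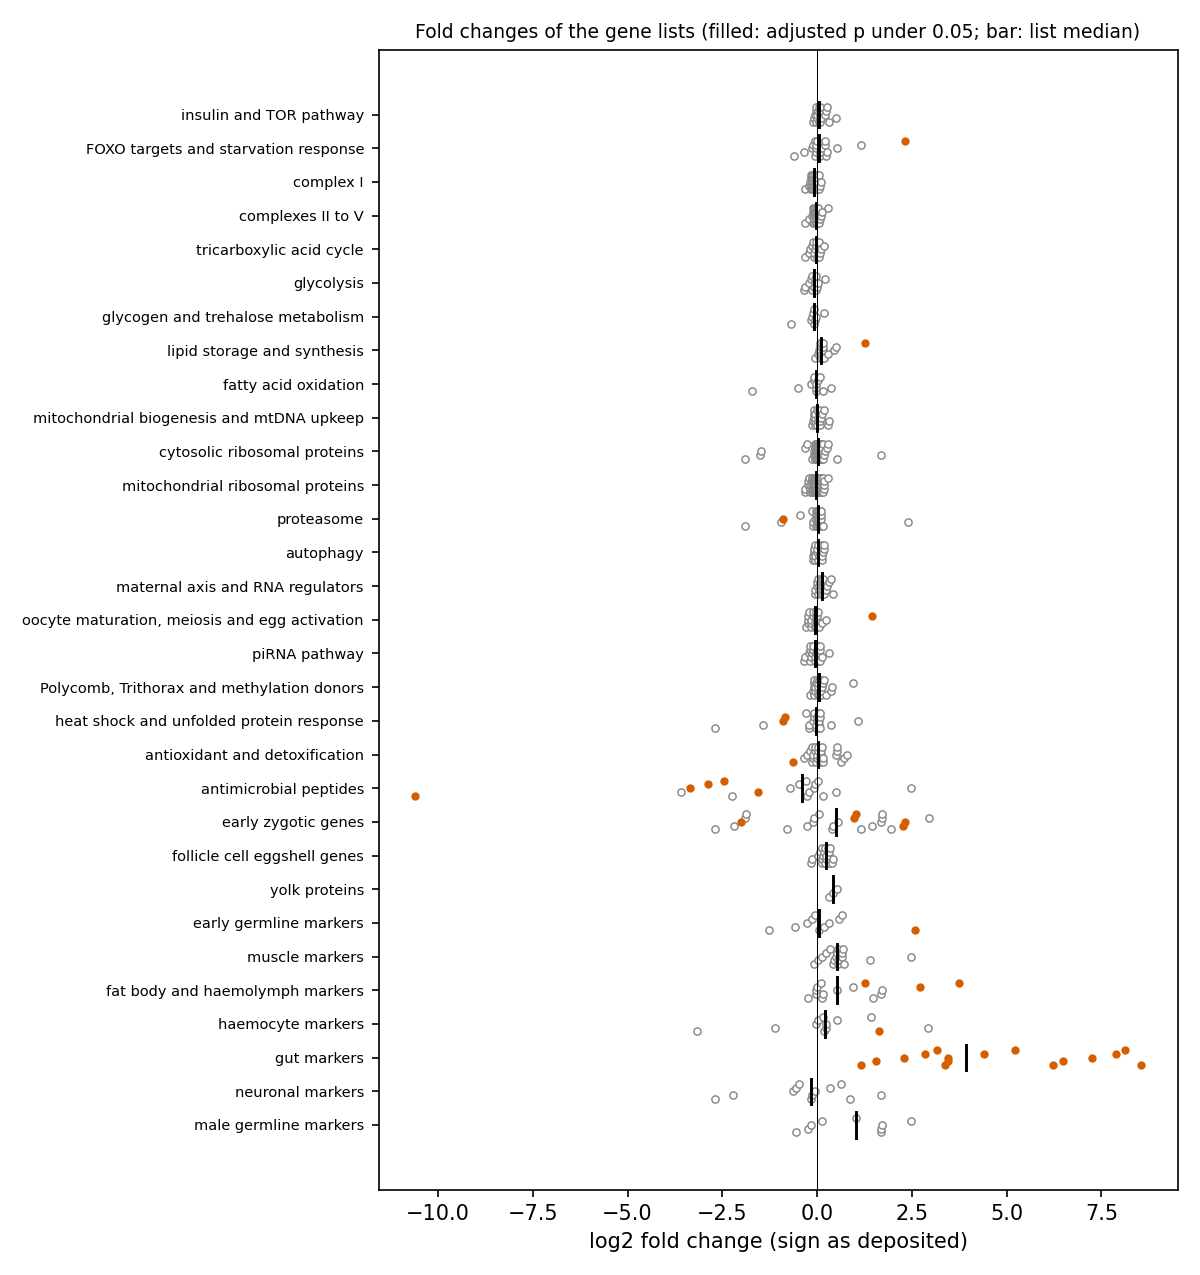
Each circle is 1 tested member of a gene list, placed by its log2 fold change in the authors' deposited table, with the sign deposited, and the bar is the list median. Filled circles have an adjusted p under 0.05. All 16 gut markers are filled and positive, 5 of 18 antimicrobial genes are filled and negative, and no insulin pathway gene is filled.

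Protein synthesis and turnover likewise held few calls. No gene was called among 92 cytosolic ribosomal protein genes, of which 1 had an unadjusted p under 0.05, among 75 mitochondrial ribosomal protein genes, of which 0 did, or among 20 autophagy genes, of which 0 did. The intervals were wide for the cytosolic ribosomal proteins, where only 34 of 90 lay within a 2-fold change, so that moderate changes were not detectable. The mitochondrial biogenesis, cytosolic ribosomal protein and proteasome lists had medians of 0.01, 0.04 and 0.03 while the set test, which they did not pass, leaned to the negative side. Among 37 proteasome genes Rpt3R, which encodes a variant of a regulatory subunit, was called at -0.91 in the authors' deposited table. Of 23 heat shock and unfolded protein genes, 2 were called, Hsp68 at -0.90 and Hsp23 at -0.84 in the authors' deposited table, the latter named after its value was seen. GstT1, a glutathione S-transferase gene, was the 1 called member of 28 antioxidant genes, at -0.62 in the authors' deposited table, and 6 of the 28 had an unadjusted p under 0.05.

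The maternal regulators of the oocyte held no called gene either. All 26 maternal axis and RNA regulators, such as those that place the body axes of the embryo, had intervals within a 2-fold change, as had all 23 piRNA pathway genes, and no member of either list was called or had an unadjusted p under 0.05. None of 29 Polycomb, Trithorax and methylation donor genes was called, and 1 had an unadjusted p under 0.05. Among 24 genes of oocyte maturation, meiosis and egg activation Cks30A was the 1 called gene. Of 32 early zygotic genes, which the embryo transcribes before it forms cells or soon after, 8 had a likelihood ratio of 0, 4 were called with positive and 1 with a negative fold change, and 7 of the 24 tested had an unadjusted p under 0.05. The authors' deposited table gave log2 fold changes of 2.33 for sisA, 2.27 for odd, 1.02 for zen and -2.0 for opa.

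Besides the gut list, 2 lists of tissue markers passed the set test, both on the positive side. The fat body and haemolymph list passed the set test with an adjusted p of 0.0089 and had 3 called members of 15, all positive, with 4 at an unadjusted p under 0.05. The larval serum protein genes Lsp2 and Lsp1beta were at 3.73 and 2.71 in the authors' deposited table, and FASN2 was the third. The adjusted p of this list was 0.065 with a preset correlation of 0.05 and 0.99 with genes of average log2 CPM below 0 left out. The muscle list passed with an adjusted p of 0.039 and none of its 18 members was called, 5 had an unadjusted p under 0.05, 17 had positive fold changes and the list median was 0.53. Tm1, a tropomyosin gene with the highest average of them, was at 0.13 in the authors' deposited table (implied SE 0.30). The adjusted p of the muscle list was 0.20 with a preset correlation of 0.05 and 0.12 without the genes of average log2 CPM below 0. Of the haemocyte markers 3 of 12 had an unadjusted p under 0.05 and 1 was called, the peroxidasin gene Pxn at 1.64 in the authors' deposited table, and of the early germline markers 2 of 11 had one and 1 was called, the meiotic cohesion gene ord at 2.58 in the authors' deposited table. A second early germline gene, CG8316, was called when adjusted over the list alone, with a negative fold change of -1.26 in the authors' deposited table.

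Follicle cell, yolk, neuronal and male germline markers gave no called gene. The 22 eggshell genes had a median log2 fold change of 0.22, with 20 positive, and 0 had an unadjusted p under 0.05. The chorion gene Cp15, with the highest average of them, was at -0.15 in the authors' deposited table (implied SE 0.60). The yolk protein genes Yp1, Yp2 and Yp3 were at 0.51, 0.42 and 0.32 in the authors' deposited table, and 0 of the 3 had an unadjusted p under 0.05. Unadjusted p were under 0.05 for 3 of 12 neuronal and 1 of 9 male germline genes. The neuronal gene elav was at 0.35 and the testis gene S-Lap1 at 1.70 in the authors' deposited table, with implied SE of 0.33 and 1.56.

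Gene calls rest on the likelihood ratio test in the authors' deposited table, and list calls on cameraPR of limma with Benjamini-Hochberg adjustment over the 30 lists with 5 or more tested members, of which the 26 that did not pass had adjusted p of 0.66 or more. Without values per sample it is not known whether 1 sample carried a call or whether the lower group held any reads. The largest fold changes are therefore fitted values and not bounds, and their implied SE do not measure their precision. The title of the table names embryos, and the description of the InR-DN samples uses the word progeny. It therefore stays open whether the table covers these oocyte samples.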

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

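The tests in this part were chosen after the values were seen. A signal outside the comparison itself appeared in 59 genes that had a fold change of 0 and a likelihood ratio of 0 although their average log2 CPM in the authors' deposited table was above 1. The 59 were among 1782 genes with no likelihood ratio, and 23 of them had an average above 3. The highest averages in the authors' deposited table were 5.86 for slp2 and 5.70 for sna, which are patterning genes of the embryo, named after their values were seen.

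A gene without reads in either compared group could keep such an average if libraries outside the 2 groups entered the same fit, but the 59 genes prompted this explanation and cannot also test it. A second explanation, that the compared libraries were embryos at the onset of zygotic transcription, is not decided. Of 29 early zygotic genes with an average log2 CPM above 1, 6 had a likelihood ratio of 0, which are among the 59, and 23 had one above 0. Which libraries entered the fit, and whether the embryos in the title of the table were unfertilised, very young or a slip for oocytes, stays open. The description of the InR-DN samples uses the word progeny, which leaves embryonic material among the open explanations, and no biological explanation was tested.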

How the results depend on the processing

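No paired analysis was possible because the authors' deposited table has no values per sample. For the same reason the planned changes of normalisation (size factors, upper quartile), of the low-count filter, of the test (quasi-likelihood against likelihood ratio, Wald test, voom), the replicate block, the omission of each sample, the set tests with an estimated correlation and with fry, the pseudocount, and the count over other splits of the samples were not run, so whether other groupings of the samples give as many calls is unknown. The planned thresholds kept both counts within 1.5 times the 342 positive and 325 negative genes, with 246 and 244 at an adjusted p under 0.01 and 280 and 289 with a fold change of at least 2. The other alternatives were chosen after seeing the data. Leaving out genes with no likelihood ratio added 13 positive and 9 negative genes. Counting once the called genes with equal values gave 338 and 322, where fold changes and averages were compared to 3 decimals and likelihood ratios to 2. Leaving tissue markers and digestive families out of the count gave 308 and 322. Leaving out genes with an average log2 CPM below 0 before adjustment gave 209 and 135, all 344 of which were among the called genes, because the genes left out include many called ones. Against 4 lists past the set test as reported, 6 passed with ranks in place of values, which kept those 4 and added complex I on the negative and eggshell genes on the positive side, 2 passed with a preset correlation of 0.05, 2 with Fisher's exact test of called genes, and 1, the gut list, without genes of average log2 CPM below 0; for the correlation and Fisher's test the 2 were the gut and antimicrobial lists, and the cause was not tested. The adjusted p of the antimicrobial list ranged up to 0.025 over its alternatives. These lack the omission of genes of average log2 CPM below 0, where too few members of that list remained. The adjusted p of the fat body list ranged up to 0.99, reached under that omission, and that of the muscle list up to 1, with Fisher's exact test. The range of the antimicrobial list is thus not comparable with these 2. Of the 51 named genes, 7 called ones were themselves left out with the genes of average log2 CPM below 0, and of the 44 others 43 kept their side of the threshold there, while sala lost its call with an adjusted p of 0.054. Depth is unknown and sets no limit that can be stated here.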

Other observations

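Gene families outside the fixed lists are given as counts of calls without a test of the family, and they were chosen after the values were seen, as were all the tests in this part. Odorant-binding protein genes had 5 called members of 29 tested, all negative, with a family median of -0.26, and the authors' deposited table gave Obp56a a log2 fold change of -7.63 and Obp57a one of -6.29. The transporter genes Oatp58Dc, Oatp58Db and Oatp58Da, neighbours by name, were at -3.26, -3.06 and -1.50 in the authors' deposited table, and no other of the 8 Oatp genes, whose median was -0.42, was called. The Npc family of sterol transport had 3 negative calls of 10 and a family median of -0.25, with Npc2c at -3.13 in the authors' deposited table. Of 7 immune-induced molecule genes, with a median of -2.20, 4 were called and negative, from -2.20 for IM2 to -5.40 for IM23 in the authors' deposited table. The average log2 CPM of Obp57a, Npc2c and IM23 were low, at -2.73, -2.76 and -3.15 in the authors' deposited table. Cytochrome P450 genes went both ways, with 9 positive and 7 negative calls among 82 and a median of -0.04, and the related Cyp4p2 and Cyp4p3 were at 2.21 and -1.81 in the authors' deposited table. Of 245 snoRNA genes 6 were called, all positive, which is a lower share than the 5.10% of all tested genes, and the family median was 0.53 against 0.03 over all tested genes, while 0 of 90 microRNA genes (median 0.33) and 0 of 47 histone genes (median 0.14) were called. Uro, which encodes the urate oxidase of the Malpighian tubule, was at -4.38 in the authors' deposited table. The most abundant row of all, the 18S ribosomal pseudogene CR41602, had an average log2 CPM of 15.47 and a log2 fold change of 0.09 in the authors' deposited table.

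Called genes were also crowded in 1 stretch of a chromosome, the only one compared with random placements. Among 12919 tested genes placed in order, the fullest window of 25 neighbours held 13 called genes, against at most 11 and a median of 6 in 10000 random placements of the calls. It lies on chromosome arm 3R and ends at CG10560, and 12 of the 13 were negative, with CG10514 at -3.51, CG11892 at -3.19 and the 1 positive gene, CG11893, at 2.44 in the authors' deposited table. Many of these neighbours belong to a family of ecdysteroid kinase-like genes, so that reads shared between related copies were not excluded.

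The median of the positive digestive list, 3.93, lies above the highest median, 0.89, of 10000 lists matched on average log2 CPM. The medians of the matched lists had themselves a median of 0.06, so a general lean of genes with such averages to the positive side is argued against. The gut values prompted this question, and the matched lists were drawn from unrelated genes, so co-expression within the list was not matched. Which libraries enter that average is not stated, so an effect of few reads in the compared samples is not excluded. Gut RNA in the libraries of 1 group is a candidate explanation, but the 16 of 16 members called positive prompted it and cannot also test it. Jon65Aiv, with the highest average of them, was at 3.36 in the authors' deposited table. Digestive enzymes outside that list were mixed, with 13 positive calls, 3 negative calls and 13 without a call among 29, and etaTry, lambdaTry and LysX had log2 fold changes of -1.80, -0.94 and -2.07 in the authors' deposited table. Gut RNA and an untested effect of the genotype stay open, and how many of these genes the oocyte itself expresses is unknown.

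The negative antimicrobial genes were weighed in the same way. A lean of genes with low averages to the negative side is not decided. Only 5 of 10000 matched lists held as many negative calls as the 5 of this list. Those 5 calls prompted the question, and the matched lists were drawn from unrelated genes. The list median of -0.39 was not extreme, as 5.44% of matched lists lay as low. Among 4435 tested genes with average log2 CPM from -4 to 0, 187 were called negative and 122 positive. Fat body tissue on the negative side, a candidate source of these peptides, is not decided by the fat body list, since its 3 called genes were positive but had averages below 0 on the log2 CPM scale, and the apolipophorin gene Rfabg, at 0.14 in the authors' deposited table, has a high average that would hide a small share. Spermathecal tissue on that side may be a further source, since 8 of 9 secreted proteases listed for that organ were called negative, from -9.03 for CG32834 to -6.39 for CG17234 in the authors' deposited table, but the list was written after these genes had been seen and decides nothing. The lean of genes with low averages, fat body tissue, infection and an effect of the genotype stay open, the last 2 untested.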
